A study of Drosophila melanogaster with 2 samples.

How the data were processed

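Chromatin immunoprecipitation and sequencing was done by the authors on whole embryos of a transgenic line with CG8281 fused to GFP, aged 0 to 20 hours, with an antibody against GFP. Per the labels, chromatin was sonicated to 200 to 800 bp, and the 2 libraries are biological replicates 1 and 2 of 1 group. Sample labels were copied by hand, and every replicate was assigned through them.

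The deposited lists used here are narrowPeak tables on dm6. Per the labels, the list of each replicate was called on its own alignment against a control alignment, the pooled list on both alignments together, and the optimal list was derived from the other 3 by the irreproducible discovery rate. The aligner, the peak caller and the thresholds are not given in the sources used here. The deposited columns used were the peak caller's signal value per peak, the -log10 of its q value and the summit offset in bases. The scaling of the signal is not stated, so signals were ranked and their ratios taken only within a list, apart from the correlations between the lists of the replicates. Each of the replicate and pooled lists held 30000 peaks, and 424 bp, 380 bp and 404 bp were the commonest widths in replicate 1, replicate 2 and the pooled list. The 3921 optimal peaks were found in the pooled list with the same position and signal, and were its 3921 strongest. Their signals ran from 122.7 to 56064.5 with a median of 217, and their -log10 q was 3.92 throughout, so q was not used further. In the optimal list 52 rows share an interval with another, and 1 summit lies outside its interval. Read alignments and signal tracks were not used here, so depth per sample is unknown. Intervals cover the counting error of peaks or genes only, not the difference between replicates.

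The annotation was Ensembl release 115 on the arms 2L, 2R, 3L, 3R, 4, X and Y, with the reference genome sequence of the same assembly. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. A promoter is the sequence within 500 bp of an annotated TSS of a protein-coding gene. Classes were given in the order promoter, 5′ UTR, coding sequence, 3′ UTR, other exon, intron and intergenic, and compared with 1000 random placements on the same arm outside runs of unknown bases. Overlap of replicates was compared with 1000 random placements of the peaks of replicate 2. Arms were compared by exact binomial tests, gene lists and non-coding classes by Fisher's exact test, and the medians of promoter and distal signal by 100000 permutations. Motifs and words were searched on either strand within 100 bp of the summit and in 2 flanks of the same total size centred 500 bp to either side, and compared by the exact McNemar test on peaks with the sequence in one place only. Words of 8 bases were chosen on 2L and 3L as the 10 with the smallest p and tested on 2R, 3R, X and 4. The p-values of each family were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Intervals of shares are exact Clopper-Pearson intervals at 95%.

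Tests, the 19 motifs, the 32 gene lists and the rule for named genes were fixed before the data were examined. The rule names the gene of the nearest TSS for the 12 strongest optimal peaks, CG8281, up to 3 bound members of each list by signal, the 5 genes with most summits in their bodies, and the bound members of a list below the other genes if there are 3 or fewer. The lists were Hox, maternal, gap and terminal patterning, pair-rule, segment polarity, dorsoventral patterning, Notch pathway, proneural and neuroblast, neuronal differentiation, glial, muscle and mesoderm, endoderm and gut, blood cell, tracheal and epithelial, germ cell, fat body, ecdysone response, Polycomb and trithorax group, insulator and architectural protein, cell cycle, DNA replication, cytosolic ribosomal protein, mitochondrial ribosomal protein, oxidative phosphorylation, proteasome, translation initiation factor, spliceosome, heat shock protein, odorant receptor, gustatory receptor, chorion and yolk protein, male accessory gland protein and cuticle protein genes. The symbols nos, Dl, CDC45L and SmG were not matched, because the annotation holds these 4 genes as nanos, Delta, Cdc45 and SNRPG. They were left out of their lists in the main counts and added in an alternative.

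Alternatives fixed before were each replicate's own 3921 strongest peaks in turn (without replicate 1, without replicate 2), the stronger upper part of the optimal peaks (1960), the 7842 strongest pooled peaks, promoter windows of 250 and 1000 bp, only the 5′-most TSS of each gene, GC-matched random positions for the promoter share, 10000 rotations of the bound status along the genome, strata of TSS number, a summit window of 50 bp, unbound promoters as background, swapped arms for the words, and other definitions of a shared peak. Chosen after seeing the data were GC-matched positions for all classes, the CG8281 peak in each replicate alone, the lists with the 4 renamed genes, and motif occurrences inside the 10 words left out at summits and flanks alike.

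The procedures were tested on simulated data. With 30% of 4000 peaks planted at promoters, 37.4% were found there, against 11.3% by chance. Of 200 random sets 8 had a permutation p below 0.05, and a separate first random set had a permutation p of 0.046. A planted gene list passed and 0 of 31 random lists did, and a planted word ranked 1 among the chosen words.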

Results

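CG8281 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos collected 0 to 20 hours after laying. The embryos came from a transgenic line that makes CG8281 with green fluorescent protein (GFP) at its C-terminal end, and the antibody was directed against GFP. The samples formed 1 group of 2 biological replicates, with no second condition, so no test between groups of samples was possible and each comparison below sets the peaks against the genome or its annotation. The peak lists of replicate 1, of replicate 2 and of the pooled replicates held 30000 peaks each. The optimal list, which combines both replicates, held 3921 peaks on dm6 and is the set used unless another is named. These lists give no read counts, so the sequencing depth is unknown, and intervals cover counting error only. Genes and peaks are not independent replicates.

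The strongest peak of each list lay at the promoter of CG8281 itself (FBgn0035824), the gene of the tagged protein. On chromosome 3L, where the gene spans 7912463 to 7913763, the optimal peak covered 7911586 to 7913359 and its summit lay 1 bp upstream of the transcription start site (TSS). Its signal was 56064.5 in the optimal list, 3.75 times that of the second strongest peak. In the separate lists it was 21494.9 in replicate 1, 3.09 times the second, and 34523.1 in replicate 2, 3.89 times the second. Replicate 1 held 1 further peak within 1 kb of the gene, at 7913638 to 7914061, with a signal of 20.7 at rank 16169. Signal is the authors' value, of unstated scaling, and no test across the 2 samples was made.

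**Figure D1:**
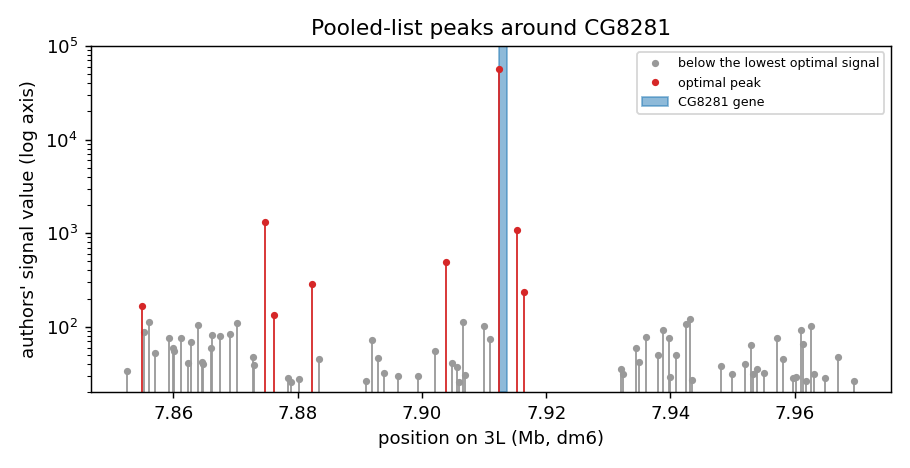
Peaks of the pooled list around CG8281 on 3L (horizontal axis, Mb; vertical axis, the authors' signal on a log axis), with optimal peaks in red, weaker pooled peaks in grey and the gene as a blue band. The CG8281 promoter peak stands at 56064.5, and 56 weaker peaks lie within 50 kb of its TSS.

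The next strongest optimal peaks lay in introns, in intergenic sequence and at promoters. The peak ranked 2 (X, 9744603 to 9745360, signal 14960.7) lay in an intron of Sp1 (FBgn0020378), a zinc finger transcription factor gene. The peak ranked 4 (3L, 8864877 to 8865742, 13530.9) lay in an intron of dally, which encodes a glypican, with CG43169 (FBgn0262788) as the gene of the nearest TSS. The peak ranked 5 (3R, 26030439 to 26031309, 12572.6) lay 1150 bp upstream of E(spl)m5-HLH (FBgn0002631), a Notch-responsive repressor gene. The peak ranked 6 (2L, 3152233 to 3153838, 12188.5) lay 86 bp upstream of a TSS of Mad (FBgn0011648), the Dpp pathway transcription factor. The peak ranked 12 (X, 522180 to 523948, 9785.29) had its summit 3 bp upstream of elav (FBgn0260400), a neuronal RNA-binding protein gene, and within the annotated gene arg. The other peaks among the 12 strongest had signals from 9794.43 to 14267.9 and lay nearest to CG10479, Sf3b3, Tm1, Dnaaf5, Hk and osp. In the replicates' own lists these 12 peaks ranked between 1 and 25 in replicate 1 and between 1 and 28 in replicate 2.

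The genes with most summits in their bodies were CG1677 (FBgn0029941) and kirre (FBgn0028369), a myoblast fusion gene, with 18 each. They were followed by sbb (FBgn0285917) with 14, bun (FBgn0259176) with 13 and shn (FBgn0003396), a zinc finger gene of Dpp signalling, with 12. Per 100 kb, shn held 20.6 summits, sbb 17.7, CG1677 14.4, bun 14.3 and kirre 4.57, beside 2.86 for the arms as a whole. These densities were not tested.

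The replicates found largely overlapping places among their strongest peaks. Of the 3921 strongest peaks of replicate 1, 2751 overlapped one of the 3921 strongest of replicate 2, a share of 70.2% (exact 95% interval 68.7 to 71.6%). Random placement on the same arms gave 2.02% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Of the 3921 optimal peaks, 2673, or 68.2%, overlapped one of the 3921 strongest peaks in both replicates. Peaks of any strength in both replicates overlapped 3721 optimal peaks, or 94.9%. No random placement was compared for either share of the optimal peaks. The optimal list was itself derived from the replicate and pooled lists, so neither share is an independent measure of how well the replicates match. Across 14867 peaks shared by the full lists, the signals had a Spearman rho of 0.629, and a Pearson r of 0.770 on the log2 scale. Among 4428 shared peaks that overlap an optimal peak, rho was 0.503.

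Summits gathered at the promoters of protein-coding genes and were nearly absent from coding sequence. Within 500 bp of a TSS lay 1383 of 3921 summits, 35.3% (exact interval 33.8 to 36.8%), against 11.5% of random positions, a ratio of 3.07. The share was 30.6% without replicate 1 and 40.3% without replicate 2. Coding sequence outside promoters held 6 summits, 0.153% (0.0562 to 0.333%), against 13.9% at random, a ratio of 0.011, and 0.0165 without replicate 2. The 3′ UTRs held 1.40% (1.06 to 1.82%) against 4.52%, and intergenic sequence 15.8% (14.7 to 17.0%) against 27.8%. Introns held 44.3% (42.7 to 45.9%) against 39.8%, and other exons 2.47% (2.01 to 3.01%) against 1.60%. Each of these 6 classes had a two-sided permutation p of 0.002, the smallest that 1000 placements can give, and an adjusted p of 0.00233 over 7 classes. The 5′ UTRs held 0.612% (0.393 to 0.909%) against 0.792%, which did not pass (permutation p = 0.234, adjusted p = 0.234).

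The 200 bp around the summits had a median GC content of 36.5%, beside 42.1% for the arms. With random positions matched for GC content, an alternative chosen for these classes after seeing the data, coding sequence was expected at 6.71% and still held fewer summits (adjusted permutation p = 0.0028). The intron excess ended there, with 43.9% expected (adjusted permutation p = 0.73), and also without replicate 2, with a ratio of 1.02 (adjusted permutation p = 0.261). The excess in other exons also ended without replicate 2, with a ratio of 1.18 (adjusted permutation p = 0.261). Counting promoters too, coding sequence lay under 0.408% of summits, and under 16.3% and 16.7% of positions 1000 bp to either side. It makes up 16.7% of the arms. Whether the peak calling treated coding sequence differently is not given in the sources used here. Of the summits of peaks ranked 20001 to 30000, 18.1% lay in it in replicate 1, 3.56% in replicate 2 and 6.08% in the pooled list.

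**Figure D2:**
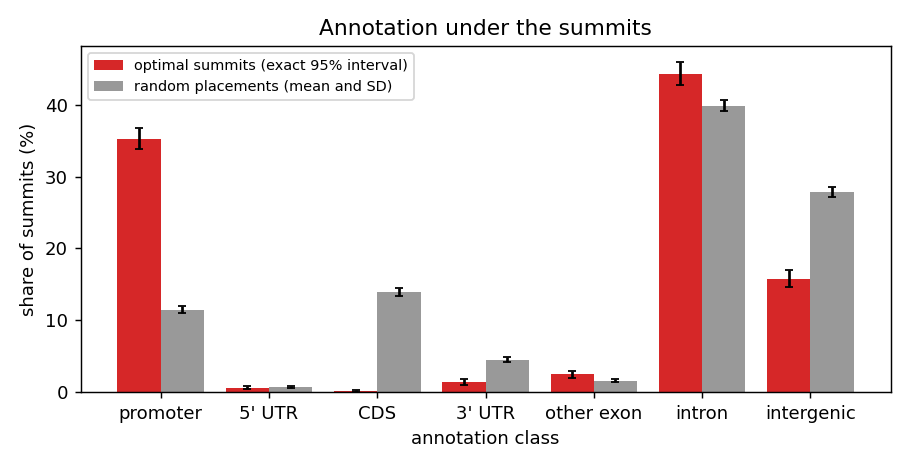
Share of summits (vertical axis, percent) in each annotation class (horizontal axis) for the optimal list, with exact 95% intervals, and for random placements, with the mean and SD over 1000 placements. Promoters hold 35.3% of summits against 11.5% at random, and coding sequence 0.153% against 13.9%.

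Promoter summits lay mostly upstream of the nearest TSS, which in some genes, such as numb and Hr78, was still inside the gene body. Of 1383 promoter summits, 1110 lay upstream of the nearest TSS, 80.3% (exact interval 78.1 to 82.3%; exact binomial test against 0.5, two-sided p = 8.04e-120). The share of 0.5 is not adjusted for the near absence of summits from coding sequence, which lies downstream of a gene's TSS. No random placement was compared here. The median position was -132 bp. Promoter peaks had a median signal of 231 and the 2538 distal peaks one of 209, a ratio of 1.11 (two-sided permutation p = 0.0002).

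The X chromosome and 3L carried more summits than their TSSs would give, and 2R, 3R, 4 and Y fewer. X held 728 summits, 1.18 times the number expected (exact binomial p = 1.70e-06, adjusted p = 1.19e-05 over 7 arms, two-sided). 3L held 835 at a ratio of 1.09 (exact p = 0.00841, adjusted p = 0.0118), 2R 714 at 0.892 (exact p = 0.000565, adjusted p = 0.00198) and 3R 900 at 0.937 (exact p = 0.0258, adjusted p = 0.0302). Chromosome 4 held 8 at a ratio of 0.356 (exact p = 0.000921, adjusted p = 0.00215). Y held 0 summits where 6.46 were expected (exact p = 0.00263, adjusted p = 0.00461). 2L, with 736 summits and a ratio of 0.987, did not pass (exact p = 0.699, adjusted p = 0.699), but turned to 1.07 and passed without replicate 1 (adjusted exact p = 0.0361). By sequence length, 2L had a ratio of 1.09 (adjusted exact p = 0.0189), X stayed above 1 at 1.08 (adjusted exact p = 0.0308), and 2R (0.987), 3L (1.04) and 3R (0.981) did not pass, with adjusted exact p from 0.249 to 0.726. The call for 3R was also lost without replicate 2 (ratio 0.951, adjusted exact p = 0.0944), and that for Y, again with 0 summits, in the stronger upper part of the peaks (adjusted exact p = 0.1). The expected numbers take no account of how well reads map to an arm or of its copy number in the embryos.

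Cytosolic ribosomal protein genes were bound far more often than other genes. A gene is called bound here if an optimal summit lay within 500 bp of one of its TSSs, which held for 1708 of 13968 protein-coding genes, 12.2%. Of 86 cytosolic ribosomal protein genes, 51 were bound, 59.3% (exact interval 48.2 to 69.8%), against 11.9% of other genes (odds ratio 10.8, Fisher's exact p = 2.87e-25, adjusted p = 9.20e-24). The share was 44.2% without replicate 1 (odds ratio 7.15, adjusted exact p = 1.14e-14) and 65.1% without replicate 2 (odds ratio 11.6, adjusted exact p = 8.66e-26). In the stronger upper part of the peaks it was 32.6%, against 6.60% of other genes (odds ratio 6.83, adjusted exact p = 2.86e-11). The strongest peaks among them lay at RpS27 (FBgn0039300; 3R, 25247359 to 25247657, signal 593), RpL34b (FBgn0037686; 3R, 9401169 to 9401540, 492.7) and RpL7 (FBgn0005593; 2L, 10200906 to 10201165, 469.8). These ranked 523, 672 and 718 in the optimal list. Their ranks were 330, 464 and 407 in replicate 1, but 1124, 1085 and 1978 in replicate 2. Most of the 51 bound genes, though not all, had weaker ranks in replicate 2, and some had no peak in 1 of the replicates. Of the 32 gene lists tested, 7 passed, 3 above the other genes and 4 below (two-sided Fisher's exact test, adjusted over 32 lists).

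Heat shock and insulator protein genes were the other lists above. Of 14 heat shock protein genes 7 were bound, 50% (23.0 to 77.0%; odds ratio 7.20, Fisher's exact p = 0.000633, adjusted p = 0.00676), among them Hsp27 (signal 694.9), Hsp83 (366.7) and Hsc70-5 (361.9), which encode chaperones. The odds ratio missed the threshold without replicate 1 (4.92, adjusted exact p = 0.0529), without replicate 2 (3.36, adjusted exact p = 0.151) and in the stronger upper part of the peaks (5.54, adjusted exact p = 0.0768). Hsc70-5 has no peak in replicate 2. Of 14 insulator and architectural protein genes 6 were bound, 42.9% (17.7 to 71.1%; odds ratio 5.40, exact p = 0.00415, adjusted p = 0.0222), among them Chro (1399.05), Cp190 (909.5) and M1BP (480.04). The odds ratio was about as large but missed the threshold without replicate 1 (4.92, adjusted exact p = 0.0529) and with only the 5′-most TSS (4.86, adjusted exact p = 0.0663). The unchanged share also missed it with rotation of the bound status along the genome (adjusted permutation p = 0.0533) and within strata of TSS number (adjusted exact p = 0.0559). Dref, also among the 6, is counted through the same peak as the ribosomal protein gene RpL13. Its summit lay 47 bp from the TSS of Dref and 37 bp from that of RpL13.

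Cuticle protein, odorant receptor, male accessory gland protein and gustatory receptor genes were bound less often than other genes. None of 77 cuticle protein genes was bound (exact upper limit 4.68%; Fisher's exact p = 7.17e-05, adjusted p = 0.00115), and the threshold was missed only in the stronger upper part of the peaks, again with none bound (adjusted exact p = 0.0768). None of 59 odorant receptor genes was bound (upper limit 6.06%; exact p = 0.000949, adjusted p = 0.00759), and with none bound the threshold was missed there (adjusted exact p = 0.134) and within strata of TSS number (adjusted exact p = 0.0582). None of 47 male accessory gland protein genes was bound (upper limit 7.55%; exact p = 0.00323, adjusted p = 0.0206), and 6 alternatives missed the threshold, with adjusted exact p from 0.0585 to 0.264. In 5 of these 6 again none was bound, and without replicate 2 it was 1 of 47, 2.13%. Of 60 gustatory receptor genes 1 was bound, 1.67% (0.0422 to 8.94%; exact p = 0.00851, adjusted p = 0.0389), and 5 alternatives missed the threshold, with adjusted p from 0.0613 to 0.134 by exact or permutation test and a share of 0 or 1.67%. That gene was Gr64a (FBgn0045479), a sugar receptor gene, with a signal of 145.8 at a summit 454 bp upstream.

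The remaining 25 lists did not pass. In the Notch pathway, 5 of 15 genes were bound, 33.3% (11.8 to 61.6%; exact p = 0.0284, adjusted p = 0.101), among them mam (signal 4331.11), numb (569.5) and E(spl)m7-HLH (401.5). That list passed without replicate 1 (40.0%, adjusted exact p = 0.0261) and in the stronger upper part of the peaks (adjusted exact p = 0.0252). With a 250 bp window its share was 20% (adjusted exact p = 0.44), and with only the 5′-most TSS 13.3% (adjusted exact p = 0.866). Of 13 ecdysone response genes 5 were bound, 38.5% (13.9 to 68.4%; exact p = 0.015, adjusted p = 0.06), among them Eip75B (438.2), Hr78 (269.4) and Eip74EF (215.3), and the list passed with a 250 bp window (adjusted exact p = 0.0261). With only the 5′-most TSS its share fell to 7.69%, below that of other genes. Within strata of TSS number, 3.45 bound ecdysone response genes were expected beside the 5 found (adjusted exact p = 0.673). Of 19 Polycomb and trithorax group genes 5 were bound, 26.3% (9.15 to 51.2%; exact p = 0.0731, adjusted p = 0.234), among them ph-p (1821.64), brm (789.6) and E(z) (625.7).

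The other developmental lists without a call held from 0 to 3 bound genes. None was bound of 8 Hox genes (exact upper limit 36.9%), 13 maternal, gap and terminal patterning genes (24.7%), 16 dorsoventral patterning genes (20.6%), 16 proneural and neuroblast genes (20.6%) or 9 blood cell genes (33.6%). In the pair-rule list 1 of 9 was bound, hry (11.1%, 0.281 to 48.2%), and in the segment polarity list 2 of 14, nkd and fz (14.3%, 1.78 to 42.8%). The neuronal differentiation list had 1 of 14, elav (7.14%, 0.181 to 33.9%). Counts of 1 in 7, each 14.3% (0.361 to 57.9%), were found in the glial list (moody), the endoderm and gut list (fkh) and the fat body list (Adh). Of 15 muscle and mesoderm genes 3 were bound, sls, tin and Tm1 (20.0%, 4.33 to 48.1%), of 12 tracheal and epithelial genes 2, trh and sdt (16.7%, 2.09 to 48.4%), and of 9 germ cell genes 2, bgcn and gcl (22.2%, 2.81 to 60.01%). Without replicate 1, the share was 42.9% in the endoderm and gut list (adjusted exact p = 0.102), 21.4% in the segment polarity list, 15.4% in the maternal list and 11.1% in the germ cell list, where bgcn has no peak in replicate 2. Without replicate 2, it was 6.25% in the proneural and neuroblast list. None of 12 chorion and yolk protein genes was bound (upper limit 26.5%).

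Housekeeping lists other than the cytosolic ribosomal proteins did not pass either. Mitochondrial ribosomal protein genes had 13 of 73 bound, 17.8% (9.84 to 28.5%), with mRpL41 (signal 2113.57) and mRpS10 (1934.17) strongest. Oxidative phosphorylation genes had 9 of 84, 10.7% (5.02 to 19.4%), with ND-B14.7 (750.8) strongest, and proteasome genes 3 of 32, 9.38% (1.98 to 25.02%), with Prosalpha7 (3168.73) strongest. Translation initiation factor genes had 6 of 44, 13.6% (5.17 to 27.4%), with eIF6 (1016.3) strongest. Spliceosome genes had 3 of 17, 17.6% (3.799 to 43.4%), with U2af50 (610.4) strongest. Cell cycle genes had 2 of 17, CycE and aurB, 11.8% (1.46 to 36.4%), and DNA replication genes 2 of 16, RnrS and Mcm2, 12.5% (1.55 to 38.3%). Like bgcn, U2af50, aurB and the proteasome gene Rpn5 have no peak in replicate 2. The same holds for some bound mitochondrial ribosomal protein and oxidative phosphorylation genes that are not named here. Without replicate 1, the share was 23.5% in cell cycle genes, 7.14% in oxidative phosphorylation genes and 11.8% in spliceosome genes. Without replicate 2, it was 17.6% in cell cycle genes and 18.8% in proteasome genes. With both replicates, adjusted exact p in the lists of this and the preceding paragraph ran from 0.438 to 1. The intervals of these lists do not exclude shares well above or below 12.2%.

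**Figure D3:**
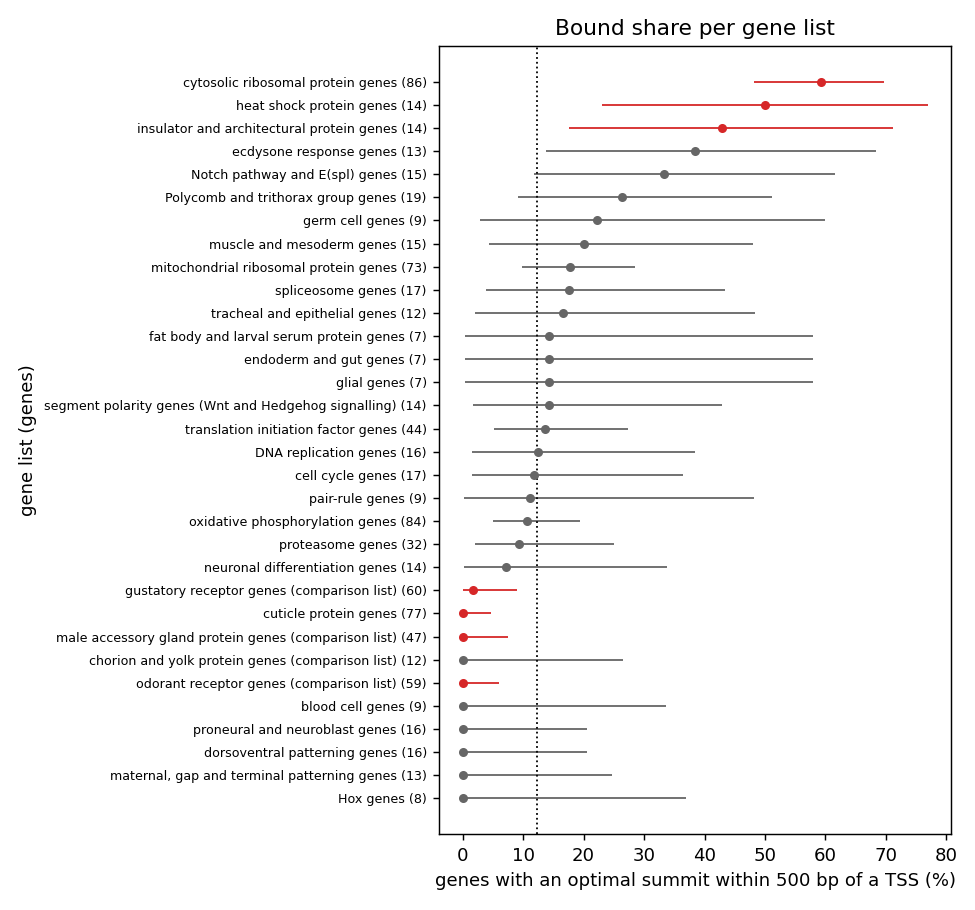
Share of bound genes (horizontal axis, percent) in each of 32 gene lists (vertical axis, number of genes in parentheses), with exact 95% intervals; red marks an adjusted Fisher's exact p below 0.05 and the dotted line is the share of all protein-coding genes, 12.2%. Cytosolic ribosomal protein genes stand at 59.3%, and cuticle protein genes at 0 of 77.

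The TATA box, the initiator, the DRE and the M1BP site were more frequent at summits than in the flanks of the same peaks, and the E-box core promoter motif was less frequent. Of 19 motifs fixed beforehand, 11 passed, 7 more frequent and 4 less frequent at summits (two-sided exact McNemar test, adjusted over 19 motifs). Flanks were not matched to summits for GC content or coding sequence, here or for the words below. Coding sequence lay under 0.408% of summits and under 12.3% and 12.5% of positions 500 bp to either side. How far the ratios follow that difference was not tested. The TATA box occurred within 100 bp of the summit but in neither flank at 540 peaks, against 293 the other way, a ratio of 1.84 (exact p = 8.97e-18, adjusted p = 1.70e-16). The initiator had a ratio of 1.41 (adjusted exact p = 4.16e-09). Its sequence, TCAGTY, lies inside some of the 8-base words described below, and without the occurrences inside any of the 10 words the ratio was 1.33 (adjusted exact p = 2.75e-06). Its ratio against unbound promoters was below 1, as given below. The DRE, the site of Dref, had a ratio of 3.35 (adjusted exact p = 2.73e-06) and the M1BP site 3 (adjusted exact p = 0.00111). The homeodomain site (1.22), the GATA site (1.20) and the BEAF-32 site (1.13) were also more frequent, with adjusted exact p from 0.00647 to 0.0466. The BEAF-32 sequence, CGATA, lies inside that of the DRE, TATCGATA, so DRE sites were also counted as BEAF-32 sites. The BEAF-32 ratio without them was not calculated. Less frequent were the Tramtrack site (0.312), the CA repeat (0.661), the E-box core promoter motif (0.714) and the Twist site (0.811), with adjusted exact p from 0.000143 to 0.0207.

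Against unbound promoters at matched distance from their TSS, 2 of the 19 motifs passed. These were the TATA box, in 20.2% of 1383 promoter summits against 14.5% of 6915 unbound positions (odds ratio 1.49, adjusted Fisher's exact p = 3.95e-06), and the homeodomain site (odds ratio 1.27, adjusted exact p = 0.0349). Their sequences, TATAAAA and TAATTA, are the only ones of the 19 made of A and T alone. All optimal summits had a median GC content of 36.5%, beside 42.1% for the arms. How far base composition accounts for these 2 calls against unbound promoters was not tested. The M1BP site (0.698), the initiator (0.855) and the BEAF-32 site (0.993) had odds ratios below 1 there, and the Twist site (1.20) and the CA repeat (1.02) above 1, each the other way than against flanks and none past the threshold. In the stronger upper part of the peaks 4 motifs passed, and the GATA site turned to 0.968. The homeodomain excess was lost without replicate 1 (1.01, adjusted exact p = 1) and in the stronger upper part of the peaks (1.11, adjusted exact p = 0.407). The DRE was lost in that part too (1.87, adjusted exact p = 0.157), as was the BEAF-32 site (1.01, adjusted exact p = 0.969). There the calls for the M1BP site (ratio 3.4, adjusted exact p = 0.0642), the E-box (0.763, adjusted exact p = 0.0644) and the Twist site (0.811, adjusted exact p = 0.161) also ended, with ratios close to those in all peaks. Calls also ended without replicate 1 for the CA repeat (0.986, adjusted exact p = 1) and the BEAF-32 site (1.13, adjusted exact p = 0.0555). Without replicate 2 they ended for the E-box (0.878, adjusted exact p = 0.157) and the GATA site (1.09, adjusted exact p = 0.294). With a summit window of 50 bp they ended for the M1BP site (2.11, adjusted exact p = 0.166), the GATA site (1.18, adjusted exact p = 0.175), the Twist site (0.786, adjusted exact p = 0.0736) and the BEAF-32 site (1.07, adjusted exact p = 0.38). Against flanks, the TATA box, the initiator and the Tramtrack site kept their calls without either replicate, in the stronger upper part and with the 50 bp window, and of these 3 only the TATA box passed against unbound promoters. The Tramtrack site there had an odds ratio of 0.359 (adjusted exact p = 0.0594), about as low as against flanks. The DRE (1.21), the E-box (0.804) and the GATA site (1.02) did not pass there either, with adjusted exact p from 0.1 to 0.912. Calls gained were those of the GAGA factor site, with a ratio of 0.877 in the main value (adjusted exact p = 0.304), and of the STAT site, with 0.844 (adjusted exact p = 0.15). The GAGA site was less frequent at summits with the 50 bp window (0.49, adjusted exact p = 0.000103) and without replicate 2 (0.722, adjusted exact p = 0.00625), but had 1.13 without replicate 1 (adjusted exact p = 0.39). The STAT site was less frequent without replicate 1 (0.741, adjusted exact p = 0.00651).

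Words of 8 bases such as ACTGACTG were more frequent at summits than in their flanks, and more so far from promoters. The 10 words of 8 bases with the smallest p on 2L and 3L all passed on the 2350 summits of the other arms 2R, 3R, X and 4. The first chosen, ACTGAATG, lay at the summit but in neither flank of 90 peaks, against 28 the other way (ratio 3.21, exact McNemar p = 8.91e-09, adjusted p = 1.11e-08 over 10 words, two-sided). ACTGACTG had the largest ratio, 143 against 17 (8.41, exact p = 5.33e-26, adjusted p = 5.33e-25), and AATGAATG the smallest, 96 against 45 (2.13, exact p = 2.10e-05, adjusted p = 2.10e-05). At distal summits ACTGACTG occurred in 7.79% of 1541 windows and in 0.649% of flanks, and all 10 words passed. At 809 promoter summits it occurred in 2.97% against 0.989%, and 2 of the 10 words passed, ACTGACTG and AGTCAGTC (each adjusted exact p = 0.0261). With the arms swapped 5 of these 10 words were chosen again, and in the stronger upper part of the peaks 8, and the 10 words chosen in each of these alternatives all passed. ACTGACTG, CTGACTGA, AGTCAGTC and GTCAGTCA are shifts or reverse complements of the same ACTG repeat, so the words are not independent. These and GTCATTCA were the words chosen again with the arms swapped. ACTGAATG was not, and AT-rich words such as ATATTTTA were chosen there. Any of the 10 words occurred at 619 of all optimal summits, 15.8%. Of 5582 sites of ACTGAATG on the arms, 182 lay within 100 bp of an optimal summit, 3.26%.

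**Figure D4:**
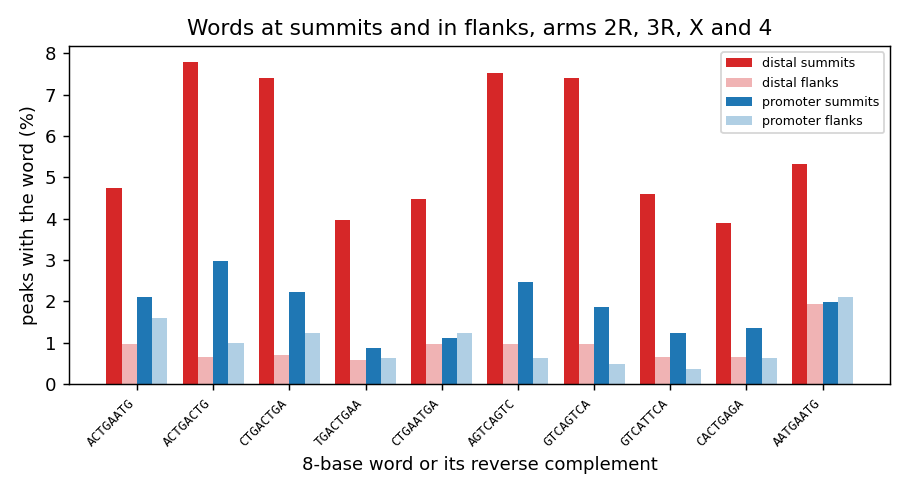
Share of peaks with each of the 10 words (vertical axis, percent; horizontal axis, word) at summits and in flanks, for distal and promoter peaks of 2R, 3R, X and 4. ACTGACTG stands at 7.79% of distal summits and 2.97% of promoter summits.

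Non-coding genes were bound less often than protein-coding ones. Of 290 tRNA genes 12 were bound, 4.14% (exact interval 2.16 to 7.12%; Fisher's exact p = 4.00e-06, adjusted p = 6.67e-06), and of 269 snoRNA genes 13, 4.83% (2.60 to 8.12%; exact p = 6.34e-05, adjusted p = 7.92e-05). Of 3289 genes annotated as ncRNA 167 were bound, 5.08% (4.35 to 5.88%; exact p = 1.65e-37, adjusted p = 8.25e-37). None of 99 rRNA genes was bound (exact upper limit 3.66%; exact p = 3.77e-06, adjusted p = 6.67e-06). Among 32 snRNA genes 1 was bound, 3.12% (0.0791 to 16.2%), which did not pass (exact p = 0.171, adjusted p = 0.171). These are two-sided tests adjusted over 5 classes. The snoRNA call was lost with a window of 1000 bp, where 14.1% were bound (adjusted exact p = 0.795). Without replicate 1, 2.60% of snoRNA genes and 9.38% of snRNA genes were bound, and without replicate 2, 6.25% of snRNA genes. Repeated gene copies leave the counts of tRNA, snRNA and rRNA genes uncertain.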

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

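The count of weak peaks around CG8281 and the test of extra copies were chosen only after the CG8281 peak had been seen, and the criterion of that test was revised after a first value had been seen.

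Around the CG8281 promoter peak the pooled list held 56 peaks below the lowest signal of the optimal list within 50 kb of the TSS, peaks compared above only where the 7842 strongest pooled peaks were taken and in the shares of coding sequence by rank. The median window of the same size held 18, and 1.78% of 13688 windows held as many. Replicate 2 had 58 (2.67% of windows as many) and replicate 1 had 35 (6.75% of windows as many).

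The height of the CG8281 peak, 3.09 to 3.89 times the second peak in the 3 long lists, may reflect extra copies of the tagged locus in the transgenic line. The strongest neighbouring peaks argue neither way: the 10th strongest within 50 kb was 1.41 times the median around the other 99 strongest peaks, and the third strongest within 10 kb was 2.81 times that median, with 3 of 99 other loci as high. The spread of single loci, 0.434 to 2.07 and 0.307 to 3.01, covers both. For the excess over the second peak, extra copies therefore cannot be told apart from binding at this promoter. The test covers only copies with at least 10 kb on each side. Against the median of the optimal list the CG8281 signal was 259 times as high. The neighbouring peaks were raised far less, which argues against such copies as the whole cause of that larger factor. Copies of the enriched words at the summit are argued against, since 0 of them lie within 100 bp of it, although the median optimal summit also holds 0. With 1 group and no untagged line among the lists used, no biological explanation was tested.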

How the results depend on the processing

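Of 551 alternative values, 443 kept their direction and their side of the threshold or stayed within their spread, 46 lost and 6 gained a call, 8 counts or correlations moved, and 48 turned direction. Of those 48, 6 had passed the threshold in the main value and 1 passed in the alternative. The GC-matched classes, the CG8281 peak in single replicates, the renamed genes and the motif counts outside the 10 words were chosen after seeing the data. The promoter share ran from 25.5 to 44.7%, the replicate overlap from 53.3 to 73.2%, and CG8281 ranked 1 in both replicates. The cause of the changes below was not tested, except that the smaller peak set has less power by construction. Of 32 lists 7 passed, but 4 to 5 without a replicate, 3 in the stronger upper part of the peaks, 4 with only the 5′-most TSS and 3 within strata of TSS number. Of 19 motifs 11 passed, but 4 in the stronger part and 2 against unbound promoters. The rank correlation of 0.629 became 0.728 with summits within 100 bp and 0.503 in optimal peaks. Turned directions were as follows. In the 7842 strongest pooled peaks, 2L had a ratio of 1.02, and the shares bound were 23.1% in the maternal list, 25% in the proneural list, 14.3% in the glial and fat body lists and 12.5% in the DNA replication list. With only the 5′-most TSS, the 5′ UTR ratio was 1.19, and the shares were 11.1% in the pair-rule list, 0 in the tracheal list and 7.69% in the ecdysone list. With 1000 bp windows, the shares were 14.3% in the segment polarity, glial, gut and fat body lists, 29.4% in the cell cycle list and 12.5% in the DNA replication list. With 250 bp windows, they were 11.1% in the pair-rule list, 0 in the tracheal and fat body lists and 10.7% in oxidative phosphorylation. Adding Cdc45 gave 11.8% in DNA replication, and none of the 4 renamed genes was bound. Within strata of TSS number, the unchanged shares of 14.3% in the glial and gut lists, 20.0% in muscle and 16.7% in the tracheal list lay below those expected. In the stronger part, 2L had 1.01, the neuronal list 7.14%, the fat body list 0, the spliceosome list 5.88%, AP-1 1.12 and GATA 0.968. AP-1 was 1.12 in 50 bp windows. By odds ratio against unbound promoters, GAGA was 1.39, M1BP 0.698, the initiator 0.855, Pho 1.07, BEAF-32 0.993, Twist 1.20 and the CA repeat 1.02. Without a replicate, the range was 0.976 to 1.07 for 2L, 0 to 15.4% for the maternal list, 11.1 to 11.1% for pair-rule, 17.6 to 23.5% for cell cycle, 9.38 to 18.8% for the proteasome, 0.722 to 1.13 for GAGA, 0.8 to 1.27 for Zelda and 0.862 to 1.01 for Pho. Depth is unknown, so no detection limit can be given. No paired analysis was possible because there is 1 group.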

Other observations

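The tests of broadly expressed genes, of transposable elements, of tandem repeats of any 4-base unit, of ACTG stretches with all 10 words, of words and signal and of words and promoters were chosen only after the results were seen; the other tests here were set out before their results.

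The excess of the words may be a by-product of other sequence. Core promoters are argued against as the whole cause, since distal summits alone kept 73 peaks with ACTGAATG at the summit only against 15 (exact p = 2.56e-10). Of 371 summits with any of the 10 words, 0 lay within 100 bp of an annotated transposable element (exact upper limit 0.989%). Copies of annotated elements therefore did not supply the words at these summits. Only 16 of all optimal summits lay that near an element, so a large share was not possible and the 0 does not set these summits apart. Elements missing from the annotation stay open. Stretches of 3 or more ACTG units are argued against as the whole cause by ACTGAATG at 62 against 28 without them (exact p = 0.000438), where all 10 words passed. ACTGACTG fell there from 143 against 17 to 54 against 16, so much of its excess lay in peaks with such stretches. Shorter ACTG stretches were not removed, so they stay open. Repeats of any 4-base unit stay open in part: without peaks holding 12 bases of such a repeat, 7 of the 10 words passed, ACTGACTG at 40 against 11 (adjusted exact p = 0.000285), and CTGAATGA, GTCAGTCA and AATGAATG did not. With 1 group, no biological explanation was tested.

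A hypothesis that the words go with distal binding was met by any of the 10 words at 19.6% of 1541 distal summits, against 8.53% of 809 promoter summits (Fisher's exact p = 3.75e-13). A hypothesis of stronger signal was examined only for the first chosen word, ACTGAATG, and was met for it. That word lay at 5.19% of the upper 1175 summits by signal, against 2.47% of the lower 1175 (Fisher's exact p = 0.000773). The other words were not compared with signal. Both hypotheses come from the same data that were used to examine them.

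The binding of cytosolic ribosomal protein promoters, 59.3% of genes, may have other causes than the genes themselves. Broadly expressed genes in general are argued against, since 5 other housekeeping lists together had 34 of 250 bound, 13.6% (9.61 to 18.5%). A neighbouring promoter is argued against as the whole cause, since genes with no other TSS within 1 kb had 6 of 18 bound, 33.3%, against 7.10% of other such genes (Fisher's exact p = 0.00116), but with a neighbour it was 45 of 68, 66.2%, against 17.2%. The enriched words are argued against, since 1 of 52 summits at these promoters held one, 1.92%, against 7.96% at other promoters, a difference that did not pass (exact p = 0.178). Expression level was not measured and stays open, and with 1 group no biological explanation was tested.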
